A study of Mus musculus with 6 samples.

How the data were processed

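RNA was sequenced from MLO-Y4 cells in 6 libraries, 3 flow and 3 non-flow control. Per the labels' protocols, replicates were collected on separate days, libraries were made with a NEXTflex rapid RNA kit, and 50-cycle single-end reads were obtained on a HiSeq 2500. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.9, Cufflinks 2.2.1 and build mm10. The gene annotation, the counting settings and the use of strand are not given in the sources used here. Without known strand use, reads of a gene and of an overlapping antisense gene cannot be told apart.

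The authors deposited 2 tables of FPKM, fragments normalized for transcript length and for library depth, with 1 column per library. In one table all 6 columns name a library title and each of its gene identifiers occurs once. It was used for the tests. In the other, 2 flow columns carry names that match no library title, so they were used only as members of the flow group, and 22 rows repeat a gene identifier, of which the row with the higher mean was kept. No table holds counts, so no count model was fitted. Neither table holds the authors' fold changes or p-values, and depth is not stated.

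Depth was estimated from the steps of low FPKM values. In genes with 1 transcript longer than 800 nt and FPKM between 0.01 and 1, FPKM multiplied by transcript length minus 200 nt gathered at 1 value, taken as that of 1 read. In non-flow control 1, 354 of 1445 such genes lay within 0.002 log units of it, against 25 with the full length. Between 74.4% and 81.2% of these genes lay within 0.02 of a whole number of reads. The estimate returned the known depths of simulated libraries. These were built with the same 200 nt taken off, so that length itself was not tested. The depth is that of the authors' normalization and would be off if they rescaled the libraries. It was 5760000 to 19230000 reads in the table tested, and 690000 to 4720000 in the other. For the library pairs that both tables name, the tested table was 3.05 to 26.0 times deeper. Floors are given as the FPKM of 3 reads and cover counting error only. An exact 0 can be a failed estimate: 2 of 6831 protein-coding genes with a mean of at least 10 FPKM had a 0 in some library, so such values are called listed at 0. No 2 libraries held identical values, and log2 values of libraries correlated at 0.896 to 0.926.

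Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. The p-values measure the spread between 3 cultures per group. In an exact permutation test, 3 against 3 cannot give a two-sided p under 0.1, so none was run on single genes. Before the data were examined, 31 gene lists were fixed. The 30 with at least 3 tested members were tested with camera at its preset correlation of 0.01, two-sided, Benjamini-Hochberg adjusted over lists, and again with an estimated correlation and with fry. A call lost with an estimated correlation does not by itself show that correlated members made it. Without pairs the estimated correlation of the hypoxia list was 0.49, above the preset. With adjacent titles as pairs it was -0.03, below the preset. The list's camera p with pairs still went from 7.62e-12 to 0.0179 (adjusted p = 0.509). The endothelial list had 2 tested members (Eng and Egfl7) and was not tested. The camera test used its default variance model. With the variance trend of the gene test, which was also run after the data were examined, 14 lists were called and not 12. In fry the p tests whether the members moved, on balance, one way.

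Named genes followed a rule fixed beforehand. It takes up to 12 called genes per direction with no overlap between groups (here 1 each), the up to 4 tested members of each list with the smallest p, and 10 genes always, whether tested or not. This gave 127 genes. The text gives the 10 and examples of the rest, and which examples was decided after their values were seen. Slc2a1, the genes of the paired protein-coding fit and the 3 genes called in the other deposited table are named for other reasons, given with them. A member of the cholesterol list is not reported here. Gene coordinates, types, transcript lengths, GC content and exon overlaps came from GENCODE M21, which uses the same mm10 assembly, and are 1-based.

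The labels' protocols put the replicates on separate days and the controls in parallel, but no label says which flow and control libraries share a day, and the fit without pairs is the main one. The title numbers of non-flow control and flow are 3 and 4, 11 and 12, and 19 and 20 for replicates 1 to 3. If adjacent titles share a day, the main fit leaves differences between days in its error. A fit with adjacent titles as pairs was planned as an alternative. The check of whether adjacent titles deviate together gave different answers by measure and is described with the alternatives, so the pairing is treated as not established.

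Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, median-ratio scaling, quantile normalization, robust moderation, the paired fit, omission of each library, and the other set tests. Added later were the other deposited table, protein-coding genes alone, the same with pairs, a GC correction without and with pairs, omission of flow libraries 1 and 2 together, and further set tests. The GC correction subtracted, in each library, a loess curve (span 0.3) of log2 deviation from the gene mean on GC content.

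The steps were tested on simulated data for the flow against non-flow comparison over 10460 protein-coding genes with 3 libraries per group, drawn from the observed means and moderated spreads, with 200 genes changed. limma recovered 89.6% of 67 genes changed 2-fold, 100% of 67 changed 4-fold and 100% of 66 changed 8-fold. Of its calls 6.76% were false. Noise was drawn independently for each gene and library, with no day effect and no GC trend, so recovery in the data can be lower. Over protein-coding genes in the data, Bnip3 changed 3.60-fold on the scale tested and was not called (limma, adjusted p = 0.224). A lack of calls therefore does not show that changes of these sizes were absent. A list shifted by -0.5 was called, with 0 of the other 29. Members were simulated as independent, while in the data the estimated correlation was 0.74 for glycolysis and 0.84 for mitochondrial transcripts. The lack of false list calls therefore does not carry over to the data. In a simulated GC trend in 2 flow libraries the correction took the correlation of fold change with GC content from 0.836 to -0.00047. It left a list shifted by -0.5 at a median of -0.409. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.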

Results

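Gene expression was measured by RNA sequencing in MLO-Y4 cells, a mouse cell line with features of osteocytes, the cells embedded in bone matrix. In 3 cultures the cells were exposed for 2 h to oscillating fluid flow at a shear stress of 10 dyn/cm² and harvested after a further 2 h in fresh medium. The 3 non-flow controls were sham-treated in parallel. The comparison asks which transcripts differed between flow and non-flow cells at this time. Values are FPKM as deposited by the authors, with 1 value per gene and library. The depth read from the smallest steps of the FPKM values was 17910000, 18080000 and 19010000 reads in non-flow controls 1 to 3. It was 11020000, 5760000 and 19230000 reads in flow libraries 1 to 3, so flow libraries 1 and 2 were the shallowest. At these depths 3 reads on 1 kb of effective length equalled 0.156 to 0.521 FPKM. Between 11507 and 11697 genes reached 1 FPKM in each library. Fold changes below are flow minus non-flow control on the log2(FPKM + 1) scale, which understates the change of low genes.

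As groups, glycolysis and hypoxia-response transcripts were lower in flow cells, and chemokine and NF-kB target transcripts were higher, by camera with a preset correlation. None of these 4 calls held with an estimated correlation (adjusted p = 0.85 for each). With few libraries that test can also lose a list of uncorrelated members, so the loss does not show that correlation made the calls. In the fit that made the calls, however, the estimated correlations lay above the preset of 0.01. They were 0.74 for glycolysis, 0.49 for hypoxia, 0.53 for NF-kB targets and 0.29 for chemokines. If these estimates hold, the p-values at the preset correlation are too small. Over single genes little passed the test: of 11957 genes, limma called 2 at an adjusted p under 0.05, with 1 higher and 1 lower in flow. Without adjustment 1019 genes had p under 0.05, 443 of them higher and 576 lower. The balance turned with quantile normalization, to 532 higher and 502 lower, and with a GC correction of protein-coding genes, to 368 and 345. It also turned without flow library 3, where 3088 genes had an unadjusted p under 0.05 (limma), 1554 higher and 1534 lower. Omission of any other single library gave 472 to 605 such genes. In 15.1% of genes the 3 flow values lay all above or all below the 3 control values, where chance gives 10%. Both called genes were short non-coding RNAs. A fit of protein-coding genes alone, chosen after the data were examined, called 0. It called 15 with adjacent titles as pairs, a pairing that is not established, and these are given with the alternatives. In the main fit, omission of any 1 library raised the number of calls, to between 9 (without flow library 1) and 24 (without flow library 3). Omission of non-flow control 1, 2 or 3 gave 10, 11 and 11 calls, and omission of flow library 2 gave 14. Without both shallow flow libraries 75 genes were called, with flow library 3 alone in its group, so that the controls gave the whole spread and the flow library was assumed to vary like them.

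The gene higher in flow was HOXA11-AS1_1 (ENSMUSG00000098717), a 96-nt RNA on chromosome 6 at 52246009 to 52246104 of mm10, whose exon lies wholly inside Hoxa11os on the same strand. It was listed at 0 in the 3 non-flow controls and at 122.7, 173.6 and 62.9 FPKM in flow libraries 1 to 3 (limma, adjusted p = 0.00514). The call was lost with adjacent titles as pairs (adjusted p = 0.110). In the other deposited table it had 211.1 FPKM in 1 flow library and at most 1.39e-08 in the other 5 libraries (adjusted p = 0.751). The gene lower in flow was Gm23966 (ENSMUSG00000094245), a 107-nt small nuclear RNA on chromosome 1 at 58466515 to 58466621. It had 19.4, 18.9 and 18.0 FPKM in the controls and was listed at 0 in the 3 flow libraries (adjusted p = 0.00030). It was listed at 0 in all 6 libraries of the other table. For Gm23966, FPKM multiplied by the depth gave 346.9, 341.5 and 341.8 in the 3 controls, equal within a factor of 1.02. Such equal products would arise if each control held the same number of reads, which could be as few as 1. The control SD of 0.708 FPKM would then reflect the steps of the values. The adjusted p of Gm23966 need not measure variation between cultures. The flow values of HOXA11-AS1_1 ran opposite to depth. They were highest in flow library 2, the shallowest at 5760000 reads, and lowest in flow library 3, the deepest at 19230000 reads. A few reads per library could give such values, so its adjusted p carries the same limit. Both RNAs are shorter than the fragment length of 200 nt assumed for the depth estimate, so no read number is given for them.

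Glycolysis genes, which encode the enzymes that turn glucose into lactate, were lower in flow as a group. All 16 measured members had a negative log2 fold change, with a median of -0.56 (camera, adjusted p = 1.38e-10). The call was lost with an estimated correlation (adjusted p = 0.85) and with fry (adjusted p = 0.38). No member passed over all genes tested in the fit without pairs. Adjusted over the list alone, 13 fell, and in 13 the 3 flow values lay below all 3 controls. Among them was Eno1 (ENSMUSG00000063524), the gene of enolase, at 687 ± 17.3 FPKM in controls and 469.6 ± 60.2 in flow (SD, n = 3), a log2 fold change of -0.56 with SE 0.11. Enolase has a near-identical copy in the mouse genome, so its value is uncertain. Gpi1, glucose-6-phosphate isomerase, had 233.8 ± 18.0 and 157.7 ± 25.4 FPKM. Pgk1, phosphoglycerate kinase, had 132.2 ± 8.15 and 101.5 ± 6.11 FPKM, and Pgam1, phosphoglycerate mutase, had 40.7 ± 3.38 and 29.0 ± 2.85 FPKM. Each of these 4 had an adjusted p of 0.0199 over the list alone.

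Hypoxia-response genes, induced in many cells when oxygen is low, had a median log2 fold change of -0.71 (camera, adjusted p = 8.11e-10), with 16 of 17 measured members below 0. This call too was lost with an estimated correlation (adjusted p = 0.85) and with fry (adjusted p = 0.38). With adjacent titles as pairs, which is not established, fry called hypoxia (adjusted p = 0.0299) and glycolysis (adjusted p = 0.0306). Camera with pairs and an estimated correlation called neither (adjusted p = 0.509 for each). No member passed over all genes in the fit without pairs, and 11 fell when adjusted over the list alone. Bnip3 (ENSMUSG00000078566), a mitochondrial protein of the BCL2 family, on chromosome 7 at 138890836 to 138909519, showed the clearest fall. Its level was 61.7 ± 14.0 FPKM in controls and 16.5 ± 4.07 in flow (SD, n = 3), a log2 fold change of -1.85 with SE 0.23 and an adjusted p over the list alone of 0.00284. Another gene on the opposite strand shares 22.3% of its exon bases. Pdk1, a kinase that restrains entry of pyruvate into mitochondria, had 23.0 ± 4.47 and 9.94 ± 4.13 FPKM. Mxi1, a MYC antagonist, had 7.95 ± 3.10 and 3.27 ± 0.418 FPKM, and P4ha1, a collagen prolyl hydroxylase subunit, had 81.2 ± 8.44 and 58.7 ± 3.22 FPKM. These 3 had an adjusted p over the list alone of 0.0183. The glycolysis and hypoxia lists share 1 gene, Slc2a1, which encodes the glucose transporter GLUT1 and is named here because both lists hold it, not by the rule fixed beforehand. It fell when adjusted over either list alone (adjusted p = 0.0238 and 0.0260), with 181.0 ± 60.8 FPKM in controls and 84.1 ± 37.1 in flow. In the later fit of protein-coding genes with adjacent titles as pairs, limma called Bnip3 (adjusted p = 0.00946), Pdk1 (0.0474) and Slc2a1 (0.0381). With GC correction as well, Bnip3 alone was called (adjusted p = 0.0220). After removal of the GC trend described below, in protein-coding genes, the medians were -0.45 and -0.79, with camera adjusted p = 8.21e-15 and 9.11e-15 at the preset correlation, and adjusted p = 0.795 for both with an estimated correlation. With flow library 3 alone against the controls they were -0.30 and -0.55.

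**Figure D1:**
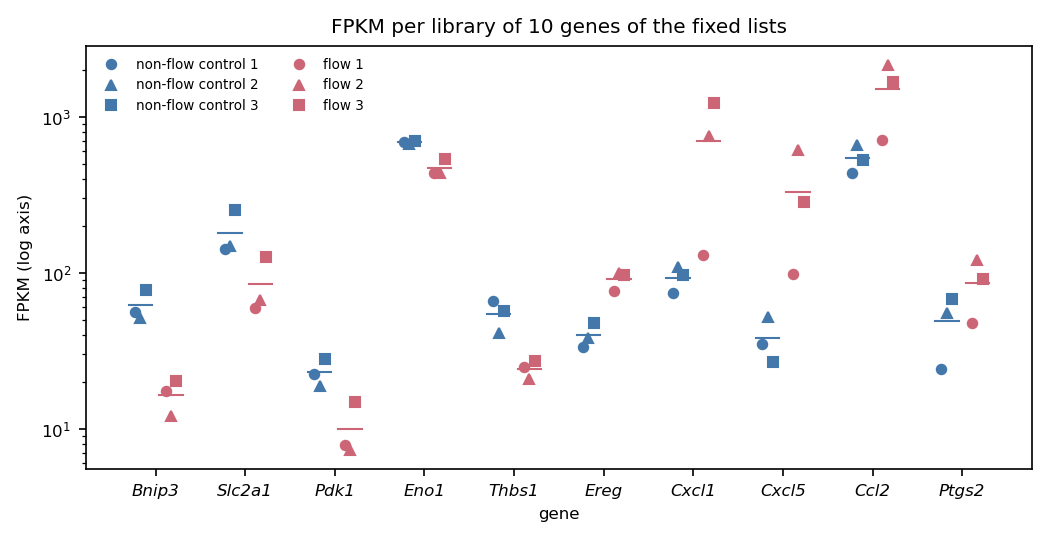
FPKM per library, on a log axis, of 10 genes of the fixed lists, picked after their values were seen, in non-flow control (blue) and flow (red), with the replicate number as the marker shape and a line at each group mean. Bnip3 lay between 51.3 and 77.6 FPKM in controls and between 12.1 and 20.1 in flow, while Cxcl1 ranged from 130.8 to 1234 FPKM within the flow group.

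Chemokine genes, which encode secreted attractants of leukocytes, were higher in flow as a group. Of 14 measured members 12 had a positive log2 fold change, with a median of 0.40 (camera, adjusted p = 0.00215). The call was lost with an estimated correlation (adjusted p = 0.85). The median was 0.25 without non-flow control 1, 0.67 without non-flow control 2, 0.17 without flow library 2 and 0.69 without flow library 3. No member passed over all genes or adjusted over the list alone. In 3 of the 14 the 3 flow values lay above all 3 controls. Cxcl5 had 37.9 ± 12.7 FPKM in controls and 330.3 ± 258.7 in flow (SD, n = 3), a log2 fold change of 2.78 with SE 0.65 and an adjusted p of 0.559 over all genes. Its 3 flow values lay above all controls. Cxcl1 had 73.6, 109.6 and 96.3 FPKM in the controls and 130.8, 748.3 and 1234 FPKM in flow libraries 1 to 3 (log2 fold change 2.42, SE 0.80). Cxcl2 had 11.9 ± 5.03 and 112.2 ± 98.9 FPKM (2.57, SE 0.96). Ccl2 had 541.5 ± 111.4 and 1511 ± 735.7 FPKM (1.35, SE 0.42), and Ccl7 had 275.0 ± 48.5 and 631.9 ± 297.4 FPKM (1.08, SE 0.40). In each of these genes flow library 1 was the lowest of the flow group.

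NF-kB target genes and inflammatory cytokines had a median log2 fold change of 0.36, with 23 of 26 measured members above 0 (camera, adjusted p = 0.000201). The call was lost with an estimated correlation (adjusted p = 0.85). The median was 0.60 without flow library 1 and 0.22 without flow library 3. No member passed over all genes or over the list alone. In only 1 member did the 3 flow values lie above all 3 controls, against 851 of all 11957 genes tested. The median deviation of members from their mean was -0.26, 0.29 and 0.35 in flow libraries 1 to 3. It was -0.23, 0.004 and -0.14 in non-flow controls 1 to 3, so flow library 1 showed no rise of the list. Vcam1, an adhesion molecule, had 135.5 ± 10.1 FPKM in controls and 201.1 ± 55.4 in flow (SD, n = 3). Saa3, an acute-phase protein, had 5.57 ± 4.36 and 13.1 ± 7.49 FPKM, and Tnfaip3, an inhibitor of NF-kB signalling, had 3.99 ± 1.87 and 7.85 ± 4.67 FPKM. Without flow library 3 both the chemokine and the NF-kB call were lost, at adjusted p = 0.0563 for chemokines and 0.126 for NF-kB targets. With GC trends removed the medians were 0.53 and 0.47 (adjusted p = 0.00116 and 8.54e-10 at the preset correlation, and adjusted p = 0.795 for both with an estimated correlation).

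Another 8 fixed lists were called by camera, 4 higher and 4 lower, and for all 8 adjusted p = 0.85 with an estimated correlation. None of their members passed over all genes or over the list alone. Higher in flow were heat shock genes (median log2 fold change 0.24, adjusted p = 0.0358), unfolded protein response genes (0.15, adjusted p = 0.0414), mitosis genes (0.18, adjusted p = 0.0173) and mitochondrially encoded transcripts (0.29, adjusted p = 0.0124). Lower were cholesterol synthesis and uptake genes (-0.31, adjusted p = 0.0157), osteoblast markers (-0.26, adjusted p = 0.0279), cytoskeleton and SRF target genes (-0.16, adjusted p = 0.0415) and interferon-stimulated genes (-0.15, adjusted p = 0.0415). Among heat shock genes, Hsph1 had 104.2, 119.6 and 105.4 FPKM in controls and 148.7, 133.1 and 133.1 in flow. Among osteoblast markers, Col1a2, a chain of type I collagen, had 123.1, 111.1 and 108.9 FPKM in controls and 96.2, 92.0 and 97.4 in flow. The log2 fold change of Col1a2 went from -0.26 to -0.06 after GC correction, and that of Hsph1 from 0.33 to 0.27. With GC trends removed, 4 of these 8 lists were no longer called: the mitochondrial list (adjusted p = 0.889), mitosis genes (0.201), osteoblast markers (0.146) and cytoskeleton genes (0.201). In the other deposited table camera did not call osteoblast markers (adjusted p = 0.249), heat shock genes (0.113), cytoskeleton genes (0.294) or interferon-stimulated genes (0.0993). Every 1 of the 8 lost its call without some single libraries, and its median moved. For mitochondrial transcripts the call was lost without non-flow control 3 (median 0.13) or flow 1 (0.04, adjusted p = 0.467), and the median was 0.49 without non-flow control 1 and 0.50 without flow 3. For mitosis genes it was lost without non-flow control 2 (0.05, adjusted p = 0.481), non-flow control 3 or flow 1 (0.06), and the median was 0.32 without non-flow control 1. For cholesterol genes it was lost without non-flow control 3 (-0.18, adjusted p = 0.436), flow 1 or flow 2 (-0.16), and the median was -0.47 without flow 3. For osteoblast markers it was lost without non-flow control 3, flow 2 (-0.13, adjusted p = 0.154) or flow 3. For heat shock genes it was lost without non-flow control 1, non-flow control 3 (0.16), flow 1 (0.14) or flow 3 (adjusted p = 0.169). For the unfolded protein response it was lost without non-flow control 1 (-0.0026), non-flow control 3 (0.08), flow 2 (adjusted p = 0.460) or flow 3, and the median was 0.30 without non-flow control 2. For interferon-stimulated genes it was lost without non-flow control 2 (-0.09), non-flow control 3, flow 1 or flow 3 (-0.01, adjusted p = 0.908), and the median was -0.25 without flow 2. Cytoskeleton genes lost it without any library but non-flow control 3 (adjusted p up to 0.148), with a median of -0.11 without non-flow control 1.

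**Figure D2:**
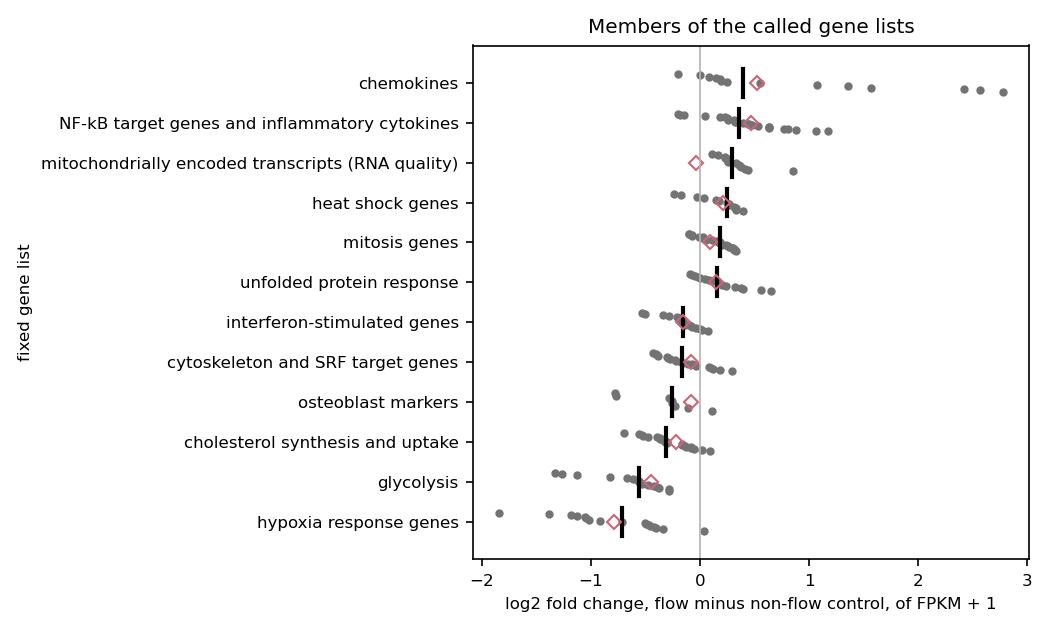
Log2 fold change, flow minus non-flow control, of each tested member (grey points) of the 12 called lists, with the list median as a black bar and the median after GC correction as an open red diamond. The glycolysis and hypoxia medians, at -0.56 and -0.71, lie farthest below 0, and that of mitochondrial transcripts moves from 0.29 to -0.04 after correction.

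Genes often studied in loaded osteocytes did not pass the test. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, had 48.8 ± 22.3 FPKM in controls and 86.4 ± 36.7 in flow (SD, n = 3; log2 fold change 0.83, SE 0.48, adjusted p = 0.567), and the groups overlapped. In non-flow controls 1 to 3 Ptgs2 had 24.15, 54.88 and 67.38 FPKM, and in flow libraries 1 to 3 it had 47.69, 120.6 and 90.95. With adjacent titles as pairs, which is not established, its SE was 0.16, and it was not called (limma, adjusted p = 0.4235). Tnfsf11, the osteoclast-inducing ligand RANKL, had 3.99 ± 1.86 and 7.61 ± 5.43 FPKM (SE 0.47 and adjusted p = 0.607, or SE 0.20 and adjusted p = 0.4235 with those pairs). Tnfrsf11b, its decoy receptor osteoprotegerin, had 1.66 ± 0.502 and 2.01 ± 0.195 FPKM (adjusted p = 0.698). Gja1, the gap-junction protein connexin 43, had 462.9 ± 45.5 and 447.8 ± 8.74 FPKM (log2 fold change -0.04, SE 0.10, adjusted p = 0.866). Sost, the gene of sclerostin, was listed at 0 in all 6 libraries. Dmp1, a matrix protein of osteocytes, was listed at 0 in the 3 controls and in flow library 2, and at 0.0354 and 0.0203 FPKM in flow libraries 1 and 3. The lists of prostaglandin genes (median -0.10 but mean 0.08, with the test toward higher, 11 measured), osteocyte markers (0.07, 10 measured), Wnt targets (-0.14, 7 measured), YAP/TAZ targets (-0.12, 20 measured), MAPK feedback genes (-0.06, 18 measured) and mechanosensors, purinergic receptors and integrins (-0.02, 17 measured) were not called, with all 6 libraries or without any 1 of them. Their medians moved with single libraries: over the 6 omissions they ran from -0.18 to 0.26, from -0.0034 to 0.11, from -0.20 to -0.03, from -0.19 to -0.05, from -0.26 to 0.11 and from -0.14 to 0.02, in the same order. Immediate-early genes had a median of -0.14 over 25 members and were not called (adjusted p = 0.314), a result that single libraries changed. The median was -0.41 without non-flow control 1 (adjusted p = 0.0128) and -0.56 without flow 3 (adjusted p = 0.0130). It was -0.27 without non-flow control 2, 0.08 without non-flow control 3 and 0.03 without flow 1, and 0.41 with flow 3 alone against the controls. Extracellular matrix genes had a median of -0.17 over 18 members and missed the threshold (adjusted p = 0.0545), but passed it without non-flow control 2 (median -0.29, adjusted p = 0.00271). Over the 6 omissions the matrix median ran from -0.29 to -0.08, and the camera adjusted p reached 0.427. In that list Thbs1 fell when adjusted over the list alone (adjusted p = 0.0186). In the list of growth and angiogenic factors (median -0.14, 14 measured) Ereg rose by the same measure (adjusted p = 0.00469). The median of that list ran from -0.25 to -0.05 over the 6 omissions.

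The flow libraries differed from each other along the GC content of transcripts. Over 10460 protein-coding genes, the rank correlation across genes between GC content and a library's deviation from the gene's mean was 0.38, 0.39 and 0.40 in the controls. It was -0.55 in flow libraries 1 and 2, and 0.40 in flow library 3. The flow minus control log2 fold change correlated with GC content at -0.62, and at -0.01 after correction. Genes are not independent replicates, so no p is attached to these correlations. Transcripts of the mitochondrial chromosome made up 20.7% and 16.1% of the FPKM sum in flow libraries 1 and 2, against 10.7% in flow library 3 and 9.40% to 13.5% in controls.

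**Figure D3:**
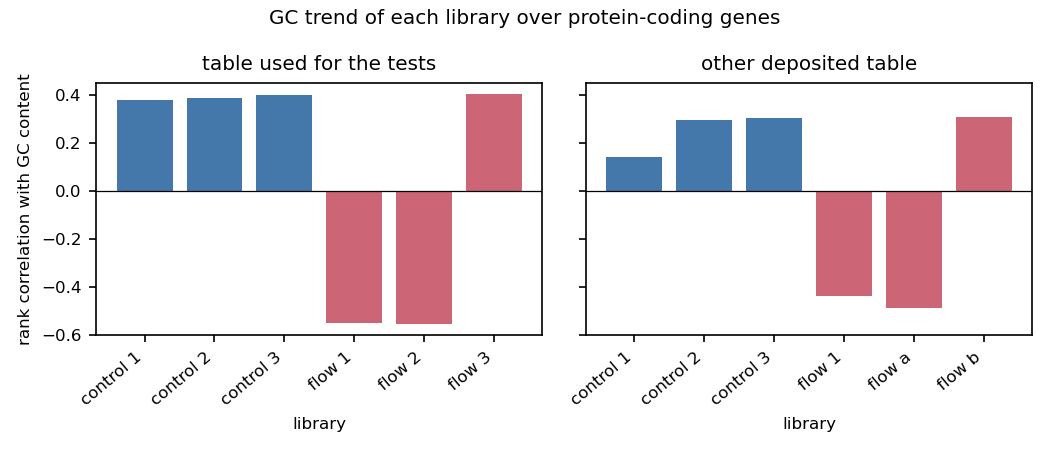
Rank correlation across protein-coding genes between GC content and the log2 deviation of each library, for the table used for the tests (left) and the other deposited table (right), with non-flow controls in blue and flow in red. Flow libraries 1 and 2 stand at -0.55 on the left, and flow library 1 and the library marked a stand at -0.44 and -0.49 on the right, where a and b are flow libraries whose sample the table does not give.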

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

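The main test called 2 genes, 1 higher and 1 lower, and 12 lists. The planned scalings, robust moderation and a minimum mean of 5 FPKM kept both gene counts at 1 and 1, and the list count at 11 or 12. Robust moderation does not enter camera. A pseudocount of 0.1 and the lack of a filter each gave 4 calls, 3 of them lower. The replicate block by adjacent titles gave 1 call with 0 higher, and 13 lists. It ended the call of HOXA11-AS1_1 (adjusted p = 0.110) and of the cytoskeleton list, added those of the immediate-early and matrix lists, and changed no other call among the named genes and lists. Omission of single libraries gave 9 to 24 called genes, 1 to 10 higher and 4 to 14 lower, and 5 to 11 called lists. With an estimated correlation or with fry 0 lists were called. A count model was not run, since no table holds counts.

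The following were chosen after the data were examined. The other deposited table gave 3 calls (Gm24853, mt-Tm and Snora33, named because they passed there), with 3 higher and 0 lower, and 9 called lists. Protein-coding genes alone gave 0 calls with limma, 0 higher and 0 lower (998 with unadjusted p under 0.05), and so did their GC correction (713). Their replicate block gave 15 calls, 2 higher (Ereg and Gm15446) and 13 lower (Bnip3, Mgarp, Ak4, Pet117, Apln, Pdk1, Slc2a1, Thbs1, Egln1, Ndrg1, Gys1, Scd2 and Osr1). Pet117 shares all its exon bases with Kat14. They are named because they passed. GC correction with the block gave 1 call, 0 higher (Bnip3), and the 15 genes had adjusted p of 0.0220 to 0.138, 12 of them under 0.1. Their median log2 change in size went from 1.18 (median SE 0.12) to 1.02 (0.10), with all 15 signs kept and single changes at 0.765 to 1.08 times the uncorrected ones. Why the calls ended was not tested. Omission of both shallow flow libraries gave 75 calls, 69 higher and 6 lower, with 7 lists, on the spread of the controls alone. With the replicate block 0 lists were called at an estimated correlation and 3 with fry: glycolysis (adjusted p = 0.0306), hypoxia (0.0299) and adipocyte and chondrocyte markers (0.0306). With GC correction and the block these were 0 and 2, glycolysis (0.0161) and hypoxia (0.0406). The medians of 3 called lists changed sign. That of the unfolded protein response was -0.00264 without non-flow control 1. The mitochondrial list had a median of -0.03886 after GC correction, without and with the block, by camera, estimated correlation and fry alike, and -0.1328 without the shallow flow libraries. The cholesterol list had 0.07303 without them. The cause of these changes was not tested. Among the 125 genes named and tested, only the 2 called ones could count as reversed, and neither did. For genes not called, 35 results of a gene in an alternative had the other sign, while 2308 results over all these genes kept sign and call status. Depth limits low genes most in flow library 2, where 3 reads on 1 kb equal 0.521 FPKM.

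Per the labels' protocols replicates were collected on separate days, but that adjacent titles share a day is a hint from the data and not stated. Pearson's correlation of deviations from the group means over 11957 genes, the measure looked at first, was 0.04, 0.02 and 0.06 in the 3 pairs. The best correlation with a library of another pair was 0.03. Over 10460 protein-coding genes, tried because the first measure was low, it was 0.29, 0.38 and 0.34. Spearman's correlation over all 11957 genes was 0.24, 0.30 and 0.28, and was computed after the paired calls had been seen. By these later measures every library correlated best with its adjacent title.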

Other observations

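Oxidative stress (NRF2) genes had a median log2 fold change of 0.16, with 8 of 14 members above 0. The list missed the threshold (camera, adjusted p = 0.0647), and passed it without non-flow control 2 (adjusted p = 0.0182) and in the other deposited table (adjusted p = 0.0235, but adjusted p = 0.87 there with an estimated correlation). Prdx1, a peroxiredoxin, had 556.1, 635.9 and 560.5 FPKM in controls and 862.9, 976.5 and 658.2 in flow, and Srxn1, sulfiredoxin, had 203.7, 286.4 and 259.7 and then 296.2, 326.3 and 358.1 FPKM. Neither passed (limma, adjusted p = 0.559). In the list of amino acid response genes (median -0.14, not called) Slc7a11, the cystine transporter subunit, had 13.1, 18.5 and 17.2 FPKM in controls and 26.0, 37.3 and 25.7 in flow (adjusted p = 0.559). S phase genes had a median of -0.06, p53 target genes 0.04, TGF-beta and BMP response genes -0.04 (mean 0.02, with the test toward higher) and circadian clock genes -0.11, none of them called. The S phase median ran from -0.10 to -0.02 when single libraries were omitted. Macrophage and osteoclast markers had a median of -0.04 over 3 members, and adipocyte and chondrocyte markers -0.15 over 3, neither of them called. The adipocyte and chondrocyte median ran from -0.42 to -0.0037 when single libraries were omitted. With GC correction and pairs, camera called that list at the preset correlation (adjusted p = 0.0159). It was not called there with an estimated correlation (adjusted p = 0.677) or with fry (adjusted p = 0.168). Replication-dependent histones had a median of 0.0065 over 4 (mean -0.15, with the test toward lower). Single omitted libraries turned the median's sign for the amino acid response, p53, TGF-beta and BMP, circadian clock, macrophage and osteoclast, and histone lists, so no direction is read from these.

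All tests below were chosen after the results they concern had been seen, except the counts over splits of the libraries. The paired fit of protein-coding genes, whose splits were also counted, was itself chosen after the data were examined. If the GC trend of flow libraries 1 and 2 were the whole cause of the lower glycolysis and hypoxia-response genes, at least 1 of the medians should lie above -0.2 after its removal. The smaller of the pair in size was -0.447 after correction, and both calls were kept at the preset correlation (though adjusted p = 0.795 with an estimated correlation and 0.38 with fry), which argues against it. In the other deposited table non-flow control 1 was the shallowest library, at 690000 reads. Non-flow controls 2 and 3 had 4590000 and 4720000 reads there, and the flow libraries 3610000 to 4620000. The smaller median there was -0.479, which argues against read depth as the whole cause. Non-flow controls 1 to 3 and flow library 1 are named in both tables, so the other one is not an independent measurement. A response to flow stays open. Both medians were lower in flow in 3 of 3 pairs of adjacent titles, which the labels do not state to be pairs. In both lists the median deviation of every control lay above that of every flow library, so any pairing would give 3 of 3. The count therefore only restates the group difference. With an estimated correlation, camera gave adjusted p = 0.85 for both lists. If adjacent titles are taken as pairs, fry gave adjusted p = 0.0306 for glycolysis and 0.0299 for hypoxia, against 0.38 without pairs.

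For chemokine and NF-kB target genes the same tests gave smaller medians of 0.466 after GC correction and 0.328 in the other table, which argue against GC content and depth as the whole cause. Both medians were higher in flow in 2 of 3 adjacent pairs. In the first pair the NF-kB median differed by -0.03 while that of chemokines was 0.48. An earlier form of this test asked for all 3 pairs and was not met, and the bound used, an opposite move beyond the spread of the pairs, was set after these values were seen. A response to flow remains a hypothesis: without flow library 3 the NF-kB median shrank to 0.22 (adjusted p = 0.126), while that of chemokines grew to 0.69 and just missed the threshold (adjusted p = 0.0563).

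Flow libraries 1 and 2, which stood apart from flow library 3 along GC content, were also the shallowest. In the other deposited table the 3 flow depths lay within a factor of 1.28, yet the rank correlations with GC content still spanned 0.794, which argues against depth. A shared day of collection would be expected to move the controls too. Control 3 differed from controls 1 and 2 by at most 0.0214, which argues against it if adjacent titles share a day. A difference in library preparation may be the source, but the labels give no batch, and no biological explanation was tested.

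The 6 libraries can be divided in 10 ways into 3 against 3, too few for a share under 0.05. In all 10 splits at least as many genes were called as in the real one, which called 2, and the highest other split called 5. A split has no direction of its own, so its larger side was counted: the real split had 1 and 1, the highest other split had 5, and 10 of 10 splits had as many. For lists 2 of 10 splits had as many, with 12 in the real split and 13 in the highest other, which sets non-flow controls 1 and 3 with flow library 1 against the rest. That split does not part all adjacent pairs. Of the 4 splits that do, the real one called 12 lists and the others 0, 5 and 5, and 4 splits cannot give a share under 0.05. For protein-coding genes with adjacent titles as pairs, only the 4 splits that part all pairs were run. The real one called 15 and the highest other 1, so 1 of 4 had as many, again too few splits for a share under 0.05.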
